A study of Homo sapiens with 6 samples.

How the data were processed

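Poly(A) RNA of MCF7 cells was sequenced as single reads of 50 bp, per the labels' design text, in 3 libraries of O-EV-treated cells and 3 of PBS-treated cells. The design text names a TruSeq stranded mRNA preparation and the extract protocol an Ultra II directional one, so the kit is not settled. Per the submitters' processing notes and the design text, the authors aligned the reads with STAR 2.4.0f1 to hg19, sorted them with SAMtools 0.1.19 and estimated expression with Cufflinks 2.0.2 on GENCODE 19. The deposited values are FPKM, as the authors' Cufflinks step gives them, 1 table with a row per gene symbol and a column per library. Cufflinks estimates how reads divide among isoforms and corrects for an effective length, which makes FPKM of very short transcripts sensitive to assumed fragment lengths. Whether the estimation used strand is not given in the sources used here, so the value of any gene that overlaps another on either strand is uncertain. Among the genes named, these include ESR1, TGFB1, MGP, ACSS2, DGAT1, ATP5I, RPS29, PLK1, CTSD, MTOR, RPS6KB2, VIM, THBS1, MDM2, GCLC, CANX and ADIRF. Of 18434 rows, 585 were 0 in every library. In 90 rows a value carried more decimals than elsewhere, as a mean over several genes of 1 symbol would; how such rows were made is not given in the sources used here. Where a gene holds the same small number of reads in 2 libraries, the ratio of its FPKM is the inverse ratio of their depths. Among genes between 0.05 and 0.3 FPKM in both libraries, these ratios peaked sharply in each pair, with 51 to 88 genes within 0.02 log2 units of the peak, and the 15 pairs fitted 1 set of relative depths to within 0.00180 log2 units. This method was checked on simulated reads. It gives relative depth only, so no counting interval or floor is given.

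Groups came from the treatment in the labels. The 11716 rows with a mean of at least 1 FPKM over the 6 libraries were transformed to log2(FPKM + 1) and tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Folds are on this scale, which understates those of low genes. Lists of genes (34 lists: metabolism, ribosomes, hormone response, signalling, stress, and other cell types) were written before the data were examined, as were the tests, the other settings tried and the rule for named genes. The 30 lists with at least 5 tested members were compared with all other tested genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. A list's error is the SE of its mean between libraries. Members were also adjusted over the list alone, with no allowance for the number of lists. The genes of mitochondrial DNA form 1 of the lists and were not analysed here. Named genes are, first, the 10 with the smallest p in each direction, since none passed the threshold, without clone-based names, pseudogenes and small RNA genes. They are also up to 4 members with the smallest p of each list, and ESR1, PGR, GREB1, TFF1, MKI67, PPARGC1A, TFAM, PLIN2, CPT1A, PDK4, ANGPTL4, AKT1, MTOR and RPS6KB1. Any other named gene was chosen after its values were seen. These are HERC6, STAT1, COL1A2, COL3A1, ADIPOQ, FABP4, PLIN1 and LPL, which are list members, and NEAT1, MALAT1, DSCAM-AS1, MIR3648, FXYD1 and NEDD8-MDP1.

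Symbols were matched to GENCODE 44 mapped to GRCh37, older symbols included (18305 rows, 99.3%), for coordinates, overlaps, length and GC content of the canonical transcript. Length was known for 11579 tested genes (98.8%). This release is later than the one the authors used. Length, median coding transcript length, coding length and GC trends were removed from each library with a spline of 5 degrees of freedom on the deviations from gene means. Library measures were compared by a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1. The other settings fixed beforehand were pseudocounts of 0.1 and 0.5 FPKM, no filter and a mean of at least 5 FPKM, rescaling to a common sum, median-ratio scaling, quantile normalization, eBayes without the trend, a replicate block, an estimated inter-gene correlation, fry, and leaving out each library. Figures and annotation used Python 3.11.15.

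The test was checked on data simulated for the 11716 tested genes with the observed means and the variances that eBayes estimated. It recovered 53.7% of 67 genes changed 1.5-fold, 89.6% of 67 changed 2-fold and 100% of 66 changed 4-fold. All these changes were simulated together, so recovery at 1.5-fold depended on the larger changes beside it. In the data, 135 genes at least 1.5-fold apart at an unadjusted p under 0.05 gave 0 calls. The simulated shares therefore do not give the power of the real comparison. Of 173 calls, 11 were genes left unchanged. With nothing changed it called 0 genes, and 530 had an unadjusted p under 0.05. A simulated shift of 0.2 log2 units in the oxidative phosphorylation list was called, with 0 lists of other genes. The lists of its complexes, shifted with it, were left out of that count. The simulated genes vary independently, unlike genes in cells.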

Results

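MCF7, an established human cell line from an estrogen-receptor-positive, luminal breast cancer, was grown with or without added extracellular vesicles and harvested on day 8. Extracellular vesicles are small membrane-bound particles that cells release. The 3 O-EV libraries came from cells given vesicles linked by the series title to women with obesity, at 1 mg/mL. The 3 PBS libraries came from cells given the same volume of phosphate-buffered saline. Both groups were treated on days 1, 4 and 7, after seeding at 40000 cells per well. Another arm named in the design text, L-EV, was not analysed here. The labels do not say whether the replicates were separate cultures or how many vesicle preparations were used. The p-values therefore measure the spread between these libraries, which may be technical. Expression was given as FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) for 18434 gene symbols, of which 11716 had a mean of at least 1 FPKM over the 6 libraries and were tested. The absolute sequencing depth is unknown, but steps of whole reads in low FPKM values gave each library's depth relative to the geometric mean of the 6. It was 1.02, 0.924 and 0.827 in O-EV replicates 1 to 3 and 0.964, 1.24 and 1.08 in PBS (two-sided exact permutation p = 0.2, where 3 against 3 allows 0.1 at the least; 0.2 adjusted over 7 library measures). The FPKM summed to 858693 ± 13833 in O-EV and 790161 ± 25120.5 in PBS (mean ± SD, n = 3 per group, as for every FPKM value below).

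The comparison of O-EV with PBS addresses how repeated exposure to these vesicles affected gene expression in the cancer cells. Genes of the mitochondrial respiratory chain and of the ribosome were slightly but broadly higher in the vesicle-treated cells. Of 79 tested nuclear genes for oxidative phosphorylation, 74 were higher in O-EV, on average by 14.9%. Of 77 cytosolic ribosomal protein genes, 75 were higher, on average by 16.0%. Both lists rose against all other genes in limma's camera test with a preset inter-gene correlation (adjusted p = 2.17e-23 and 1.88e-26). Neither call held with an estimated correlation (adjusted p = 0.164 and 0.270). Short transcripts as a whole were also higher in O-EV, and both lists hold short transcripts, with median lengths of 757 and 785 nt.

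No single gene passed the threshold in either direction: limma found 0 higher and 0 lower genes, and the lowest Benjamini-Hochberg adjusted p was 0.193. Members given below as higher or lower when adjusted over their list alone did not pass over all genes. At an unadjusted p under 0.05 there were 938 higher and 863 lower genes, 1801 in all, where chance alone gives about 586 on average. Genes do not vary independently, so a shift shared by many of them can move this count far from that average. The total was 1241 with the length trend removed, and other splits of the 6 libraries gave up to 1086. The total was 901 without PBS replicate 2, 1032 without PBS replicate 3 and 2592 without PBS replicate 1. Of these 1801 genes, 38 were at least 1.5-fold higher and 97 at least 1.5-fold lower. The 3 O-EV values lay all above or all below the 3 PBS values for 2473 genes, 21.1% of those tested, where chance gives 10%.

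Among the 10 genes with the smallest p and higher values in O-EV, ACHE, which encodes acetylcholinesterase, had the largest difference. It measured 10.004 ± 4.60 FPKM in O-EV against 1.73 ± 0.421 in PBS, a log2 difference of 1.91 ± 0.32 (SE, on the log2(FPKM + 1) scale, which understates differences of low genes). The O-EV libraries differed widely, at 12.7, 4.70 and 12.7 FPKM, and without O-EV replicate 2 ACHE passed the threshold (limma, adjusted p = 0.00875). CKB, the brain-type creatine kinase that buffers cellular ATP, measured 132 ± 2.57 FPKM in O-EV against 98.4 ± 4.64 in PBS (log2 0.42 ± 0.066). The other 8 were 1.26-fold to 1.36-fold higher on that scale. They included the small nuclear ribonucleoprotein gene SNRPE (260.0 ± 1.60 against 206 ± 4.41 FPKM), SMDT1, a regulator of the mitochondrial calcium uniporter (115 ± 6.80 against 86.2 ± 2.30 FPKM), and SAR1A, a GTPase of vesicle transport from the endoplasmic reticulum (75.7 ± 3.46 against 56.3 ± 2.70 FPKM). The mitochondrial ribosomal protein gene MRPL53 measured 183 ± 10.3 against 140.4 ± 3.47 FPKM, RPL37 of the cytosolic ribosome 3380.4 ± 200.3 against 2557 ± 118 FPKM, and USMG5, a small ATP synthase subunit, 471 ± 25.6 against 359 ± 20.8 FPKM. MYEOV2, now named COPS9, measured 294 ± 12.3 against 223 ± 8.29 FPKM, and the phosphatase gene MDP1 43.9 ± 2.35 against 32.0 ± 1.09 FPKM. MDP1 overlaps a read-through transcript, NEDD8-MDP1, so its value is uncertain. Without O-EV replicate 1 the read-through was lower in O-EV (log2 -2.26, limma, adjusted p = 0.0414), opposite to MDP1. On GRCh37, ACHE lies on chromosome 7, 100487615 to 100494594, minus strand, and CKB on chromosome 14, 103986004 to 103989170, minus strand.

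Among the 10 genes with the smallest p and lower values in O-EV, NFKBIZ, which encodes a nuclear regulator of NF-kappaB targets, came first at 12.6 ± 0.915 FPKM in O-EV against 21.3 ± 1.80 in PBS (log2 -0.71 ± 0.11). On GRCh37 it lies on chromosome 3, 101546835 to 101579866, plus strand. OGT, the enzyme that adds O-linked N-acetylglucosamine to proteins, measured 19.8 ± 0.531 against 29.1 ± 1.85 FPKM (log2 -0.53 ± 0.088). PRKDC, the catalytic subunit of DNA-dependent protein kinase, measured 25.9 ± 2.65 against 42.0 ± 6.80 FPKM, and ITGAV, the integrin alpha-V subunit, 8.06 ± 0.869 against 13.5 ± 1.69 FPKM. TBC1D4, a Rab GTPase-activating protein of insulin-regulated glucose uptake, measured 1.60 ± 0.457 against 3.99 ± 0.784 FPKM. The kinase gene WNK1 was at 18.9 ± 2.04 against 27.9 ± 1.69 FPKM, and CKAP5, a microtubule polymerase of the spindle, at 29.6 ± 1.30 against 39.9 ± 1.62 FPKM. LHFPL2 was at 4.57 ± 0.310 against 8.33 ± 0.730 FPKM and YEATS2, a subunit of a histone acetyltransferase complex, at 4.89 ± 0.341 against 8.37 ± 0.588 FPKM. CDK11A (19.4 ± 0.508 against 28.7 ± 1.96 FPKM) has a near-identical neighbour, CDK11B, and its value is uncertain. Of the 20 genes, MRPL53, USMG5, NFKBIZ and YEATS2 overlap another named gene, as MDP1 does, and are uncertain to that extent. None of the 20 genes passed the adjusted threshold with all 6 libraries. Apart from CDK11A and NFKBIZ, the lower genes had canonical transcripts of at least 4977 nt.

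**Figure D1:**
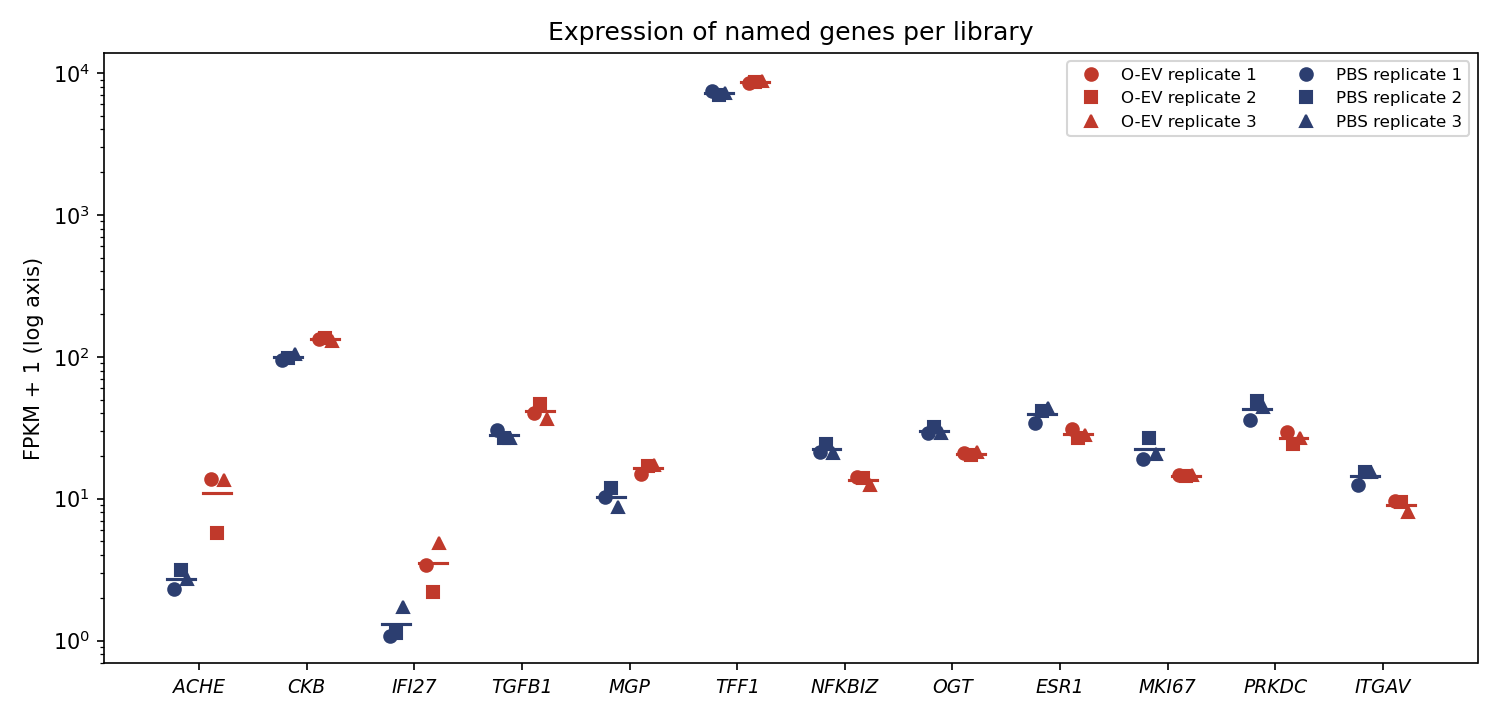
FPKM plus 1 (log axis) of 12 named genes in each library, with red symbols for O-EV, blue symbols for PBS, a symbol shape per replicate and a horizontal line at each group mean. ACHE spans 4.70 to 12.7 FPKM in O-EV and 1.31 to 2.15 in PBS, and no gene shown passed the adjusted threshold.

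Within oxidative phosphorylation, the lists for each of the complexes were higher in O-EV, with complexes II and III in 1 list. The mean log2 difference was 0.19 ± 0.034 (SE between libraries) for complex I, 0.15 ± 0.034 for complexes II and III, 0.26 ± 0.038 for complex IV and 0.22 ± 0.040 for ATP synthase. Each rose in the camera test (adjusted p = 7.75e-13, 0.00182, 2.41e-10 and 1.50e-10), and none did with an estimated correlation (adjusted p = 0.164, 0.270, 0.164 and 0.164). Over the whole list the mean difference was 0.20 ± 0.034. When each library was rescaled to the same sum, it was 0.081 (0.070 for complex I, 0.027 for complexes II and III, 0.14 for complex IV and 0.10 for ATP synthase). That scaling moved the median of all genes by -0.11, to -0.13, so a negative mean given below after it can still lie above other genes. After quantile normalization the mean of the whole list was 0.095, with 0.11 for complex I, 0.10 for complex IV and 0.092 for ATP synthase. Over all genes 0 members passed; adjusted over the list alone, 42 of 79 were higher and 0 lower. Examples were NDUFB1 of complex I (563 ± 29.9 against 428 ± 35.4 FPKM), UQCR10 of complex III (236 ± 14.4 against 188 ± 8.87 FPKM), NDUFA4, now placed in complex IV (459 ± 46.0 against 335 ± 10.9 FPKM), and ATP5I of ATP synthase (719 ± 43.0 against 559 ± 17.9 FPKM). COX5B measured 489.6 ± 39.0 against 382 ± 4.24 FPKM. With each library's trend with transcript length removed, a correction chosen after the data were seen, the list mean was 0.10 and still passed (adjusted p = 1.64e-07; adjusted p = 0.277 with an estimated correlation). Complexes II and III alone then missed the threshold (adjusted p = 0.0855), and also after quantile normalization (adjusted p = 0.350). The genes that mitochondrial DNA encodes were not analysed here.

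For the tricarboxylic acid cycle, which feeds the respiratory chain, 13 of 21 genes were higher and the list did not pass (mean log2 difference 0.035 ± 0.038, adjusted p = 0.166). Its mean was -0.083 after rescaling to the same sum, where the median of all genes was -0.13. The list passed when each library's trend with GC content was removed (adjusted p = 0.0153 at the preset correlation). SDHB, shared with complex II, measured 188 ± 14.2 against 160.4 ± 7.12 FPKM, and IDH2 281 ± 3.003 against 249 ± 20.3 FPKM. The glycolysis list rose marginally (mean 0.054 ± 0.041, adjusted p = 0.0342; 0.545 with an estimated correlation), and 0 of 21 members passed when adjusted over the list alone. The glycolysis list lay at percentile 49.0 of random gene lists matched on expression (average 0.055) and 84.6 with length matched as well (average 0.020). Its mean turned negative after rescaling to the same sum (-0.061, with the test direction still upward) and after quantile normalization (-0.0089, with a downward direction). The call was lost without O-EV replicate 1 (0.0941), O-EV replicate 3 (0.206), PBS replicate 2 (0.126) or PBS replicate 3 (0.1002), and the mean was 0.084 without O-EV replicate 2 and 0.034 without O-EV replicate 3. ALDOA measured 5482 ± 292 against 4641 ± 349 FPKM and ENO1 1569 ± 7.81 against 1386 ± 113 FPKM. Mitochondrial biogenesis regulators did not pass (10 of 27 higher, adjusted p = 0.987), with a mean of -0.024 against an upward test direction (0.0022 with the length trend removed). PPARGC1A, the coactivator PGC-1alpha, was at 2.36 ± 0.940 against 1.40 ± 0.168 FPKM (log2 0.45 ± 0.20, and 0.23 without O-EV replicate 3), its relative PPARGC1B at 1.04 ± 0.108 against 1.67 ± 0.498 FPKM, and the mitochondrial transcription factor TFAM at 13.2 ± 1.90 against 12.8 ± 1.62 FPKM. TFAM's log2 difference of 0.041 ± 0.14 was negative after rescaling to the same sum.

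The cytosolic ribosome list had a mean log2 difference of 0.21 ± 0.052, and adjusted over the list alone 50 of 77 members were higher and 0 lower. RPS29 measured 5604 ± 561 against 4068 ± 271 FPKM and RPL38 1743 ± 221 against 1272 ± 80.2 FPKM. RPS17, at 1599 ± 67.3 against 1325 ± 54.0 FPKM, has near-identical copies and is uncertain. The ribosomal genes made up 23.1 ± 0.609% of the FPKM sum in O-EV and 21.5 ± 0.544% in PBS (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows; 0.14 adjusted over 7 library measures). The list mean was 0.10 with the length trend removed (adjusted p = 4.41e-08; adjusted p = 0.366 with an estimated correlation). It was 0.094 after rescaling to the same sum. The list no longer passed after quantile normalization (mean 0.023, adjusted p = 0.188). The mitochondrial ribosome list rose as well, with 63 of 75 genes higher, a mean of 0.13 ± 0.038 and an adjusted p of 1.28e-10 (0.270 with an estimated correlation). Adjusted over the list alone, 1 member was higher, and the list mean was 0.062 with the length trend removed and 0.017 after rescaling to the same sum. MRPL52 measured 342 ± 10.9 against 278 ± 16.1 FPKM and MRPL54 95.05 ± 3.99 against 72.1 ± 10.2 FPKM. The list's median transcript length was 1224 nt.

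**Figure D2:**
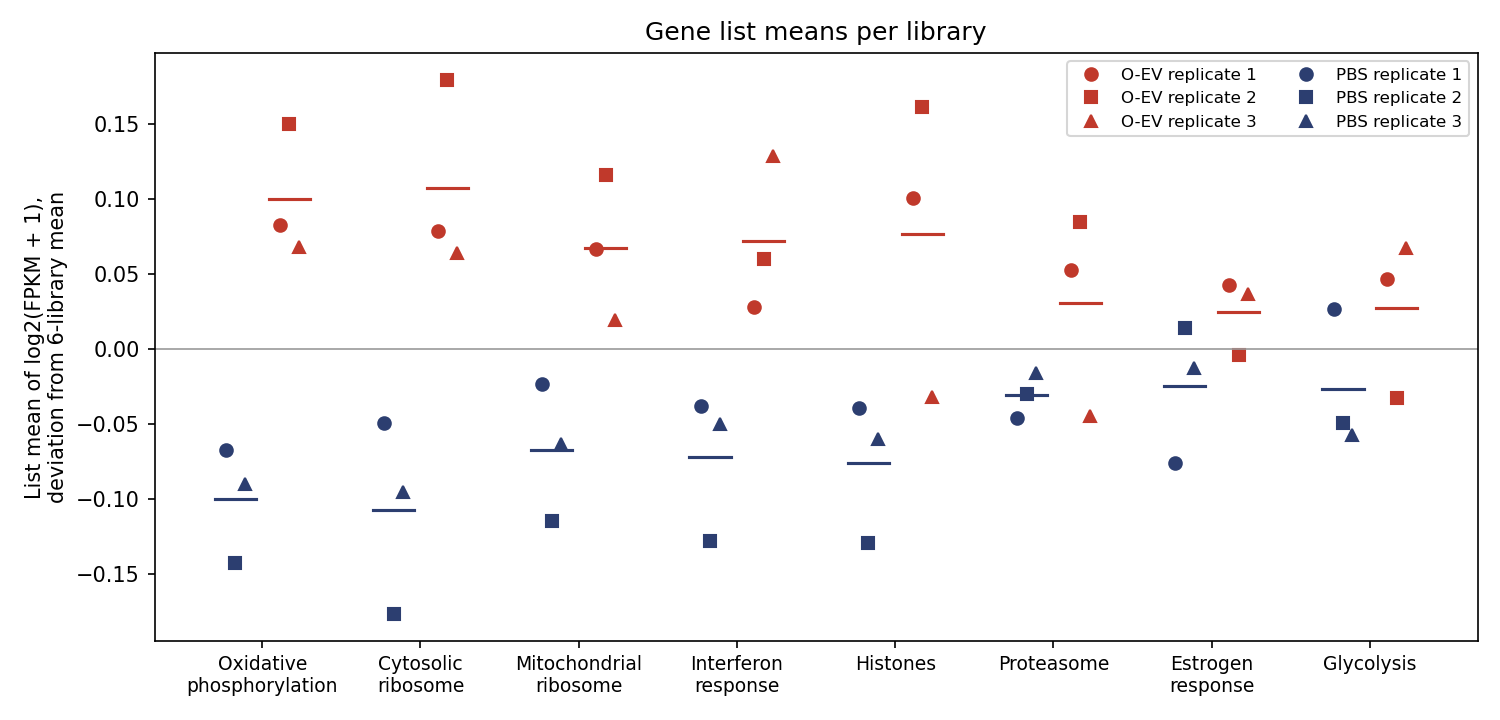
Mean of log2(FPKM + 1) over the members of 8 gene lists in each library, as the deviation from the mean of the 6 libraries (red, O-EV; blue, PBS; symbol shape, replicate; line, group mean). For oxidative phosphorylation, both ribosome lists, histones and the interferon list every O-EV library lies above every PBS library; all 8 lists passed the preset-correlation test and none passed with an estimated correlation.

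Components of the PI3K, AKT and mTOR growth pathway went both ways, and the list did not pass (13 of 26 higher, mean -0.042 ± 0.019, upward test direction, adjusted p = 0.938). Its mean turned positive with the trend with canonical, median or coding length removed (0.040, 0.011 and 0.024). Adjusted over the list alone, 1 member was higher and 1 lower. AKT1 measured 413 ± 7.95 against 359 ± 11.9 FPKM and the S6 kinase gene RPS6KB2 103 ± 4.69 against 79.3 ± 7.55 FPKM. In the other direction were MTOR (9.04 ± 1.58 against 12.6 ± 0.903 FPKM), PIK3R1, the regulatory subunit of PI3-kinase (11.7 ± 0.825 against 17.8 ± 2.27 FPKM), and RPS6KB1 (169.7 ± 27.1 against 209 ± 6.30 FPKM). None of these 5 passed the adjusted threshold over all genes.

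The estrogen response list rose slightly, with 23 of 38 targets higher, a mean of 0.050 ± 0.030 and an adjusted p of 0.0342 (0.312 with an estimated correlation). After rescaling to the same sum its mean was -0.064, with the test direction still upward and a median of all genes of -0.13. With the trend with canonical transcript length removed its mean was 0.078 and it passed (adjusted p = 0.0132; adjusted p = 0.366 with an estimated correlation). With the median length of coding transcripts its mean was 0.059 and it missed the threshold (adjusted p = 0.0930). The call was lost without O-EV replicate 1 (0.110), O-EV replicate 3 (0.167), PBS replicate 1 (0.149) or PBS replicate 3 (0.0510), and the mean was 0.024 without PBS replicate 1. Adjusted over the list alone, 2 members were higher: the secreted trefoil factors TFF1 (8669 ± 149 against 7234 ± 259.6 FPKM) and TFF3 (414 ± 14.9 against 340.2 ± 13.8 FPKM). Their canonical transcripts are short (492 and 867 nt), and their log2 differences went from 0.26 to 0.085 and from 0.28 to 0.15 with the length trend removed. The protease gene CTSD measured 2146 ± 54.8 against 1796 ± 156 FPKM and IGFBP4 229.9 ± 2.26 against 189 ± 19.1 FPKM. The receptor gene itself, ESR1, was lower in O-EV at 27.5 ± 2.24 against 38.8 ± 5.20 FPKM (log2 -0.47 ± 0.12), and GREB1, another target, was at 59.6 ± 8.30 against 67.3 ± 6.56 FPKM; neither passed. The progesterone receptor gene PGR was below the tested level, at 0.749 ± 0.0693 against 0.666 ± 0.178 FPKM. Luminal epithelial genes as a list did not pass (11 of 25 higher, mean -0.060 ± 0.038, adjusted p = 0.758). That list passed downward after quantile normalization (adjusted p = 0.00752 at the preset correlation). AR, the androgen receptor gene, was at 3.73 ± 0.671 against 5.64 ± 1.19 FPKM and the tight junction gene TJP1 at 11.2 ± 1.15 against 15.5 ± 2.402 FPKM.

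Cell cycle genes showed no shared direction (23 of 50 higher, mean -0.035 ± 0.030, adjusted p = 0.938). Their mean was -0.15 after rescaling to the same sum, 0.021 with the GC trend removed and 0.025 with the coding length trend removed. Adjusted over the list alone, 1 was higher, the ubiquitin-conjugating enzyme gene UBE2C (253 ± 9.44 against 201 ± 6.58 FPKM), and 1 lower, the proliferation marker MKI67 (13.6 ± 0.203 against 21.2 ± 4.16 FPKM). Their canonical transcripts measure 777 and 12716 nt. CDC20 was at 166 ± 10.4 against 139 ± 11.5 FPKM and PLK1 at 125 ± 9.81 against 108 ± 0.624 FPKM. The histone list rose (mean 0.15 ± 0.063, 15 of 17 higher, adjusted p = 0.000497; 0.376 with an estimated correlation). Adjusted over the list alone, 1 member was higher, HIST2H2AA3 (94.7 ± 6.44 against 72.5 ± 5.75 FPKM). With the length trend removed the list mean was -0.022 and it no longer passed (adjusted p = 0.692); after rescaling to the same sum the mean was 0.038. Most replication histone transcripts lack a poly(A) tail, and members of the family are near-identical, so values such as that of HIST1H1C (106 ± 4.65 against 85.5 ± 10.5 FPKM) are uncertain. The proteasome list rose by a mean of 0.062 ± 0.040 (adjusted p = 0.00416; 0.343 with an estimated correlation), and 0 of 31 members passed when adjusted over the list alone. It lay at percentile 11.5 of random gene lists matched on expression (average 0.095) and 8.44 with length matched as well (average 0.094). The proteasome list thus rose against all other genes but not against genes of like expression. Its mean was -0.058 after rescaling to the same sum, with the test direction still upward and a median of all genes of -0.13. It was -0.031 after quantile normalization, with a downward direction, and 0.014 with the length trend removed. The proteasome call was also lost without O-EV replicate 2 (0.0633, mean 0.035), and the mean was 0.10 without O-EV replicate 3. PSMB5 measured 594 ± 19.1 against 515 ± 2.67 FPKM and PSMB6 312 ± 6.48 against 271 ± 13.9 FPKM.

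The interferon response list rose, with 21 of 28 tested genes higher, a mean of 0.14 ± 0.041 and an adjusted p of 0.00416 (0.276 with an estimated correlation). Adjusted over the list alone, 2 members were higher: IFI27 (2.50 ± 1.34 against 0.311 ± 0.355 FPKM) and the membrane protein gene IFITM2 (115.7 ± 3.47 against 90.9 ± 7.22 FPKM), which has close paralogs, so its value is uncertain. IFI27 was at 0.083, 0.129 and 0.72 FPKM in PBS, so its log2 difference of 1.37 rests on low values and raises the list mean. The list median was 0.15. B2M, the light chain of class I HLA molecules, was at 323 ± 25.8 against 268 ± 15.9 FPKM. HERC6 was lower, at 2.11 ± 0.266 against 3.29 ± 0.657 FPKM, as was the transcription factor gene STAT1, at 24.0 ± 2.49 against 28.1 ± 3.61. The list's mean was 0.049 after rescaling to the same sum. It was 0.097 with the length trend removed, and the list then missed the threshold (adjusted p = 0.151). The call was also lost with no filter on low values (adjusted p = 0.144).

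NF-kappaB inflammatory genes did not pass (6 of 14 higher, mean -0.021 ± 0.020, adjusted p = 0.954; mean 0.022 after quantile normalization), with NFKB1 at 11.7 ± 1.42 against 14.8 ± 1.32 FPKM and the feedback inhibitor TNFAIP3 at 0.778 ± 0.0990 against 1.29 ± 0.183 FPKM. Immediate early genes leaned lower without passing (16 of 23 lower, mean -0.11 ± 0.055, adjusted p = 0.0863). That list passed with the length trend removed (adjusted p = 0.0154), without O-EV replicate 1 (0.0412) and without PBS replicate 2 (0.0342), each at the preset correlation. The length-corrected call was lost with an estimated correlation (adjusted p = 0.564). Without O-EV replicate 2 the list mean was -0.059 (adjusted p = 0.574). FOS was at 5.86 ± 1.48 against 3.92 ± 0.532 FPKM, CYR61 at 2.31 ± 0.167 against 3.22 ± 0.171 FPKM and KLF10 at 15.0 ± 2.00 against 18.3 ± 0.828 FPKM. Mesenchymal genes did not pass (mean 0.024 ± 0.022, -0.080 after rescaling to the same sum, 0.075 with the length trend removed, adjusted p = 0.510). Adjusted over the mesenchymal list alone, 1 was higher, TGFB1, the cytokine transforming growth factor beta 1 (40.3 ± 5.05 against 27.0 ± 2.10 FPKM, log2 0.55 ± 0.11). THBS1 was at 26.5 ± 4.10 against 39.3 ± 7.18 FPKM and VIM at 7.71 ± 1.86 against 5.36 ± 0.275 FPKM.

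Lipid genes did not pass as lists. Fatty acid oxidation had 8 of 22 genes higher (mean -0.022 ± 0.031, adjusted p = 0.893), with CPT1A, the gate to mitochondrial oxidation, at 37.6 ± 2.58 against 38.8 ± 1.58 FPKM and ACSL1 at 4.59 ± 0.599 against 6.60 ± 1.20 FPKM. The oxidation list's mean was -0.14 after rescaling to the same sum, 0.015 with the GC trend removed and 0.0083 with the coding length trend removed. Fatty acid and triglyceride synthesis had 8 of 20 higher, a mean of 0.029 ± 0.051, a median of -0.050 and an adjusted p of 0.748. Adjusted over the synthesis list alone, 2 members were higher: ACSS2, which makes acetyl-CoA from acetate (24.2 ± 5.59 against 14.8 ± 1.81 FPKM), and DGAT1, which makes triglycerides (51.5 ± 8.69 against 36.5 ± 0.672 FPKM). ACLY, which makes acetyl-CoA from citrate, was at 72.5 ± 4.35 against 84.0 ± 5.53 FPKM. Cholesterol synthesis had a mean of 0.036 ± 0.036 and an adjusted p of 0.320 (mean 0.0023 without O-EV replicate 2 and 0.062 without O-EV replicate 1), with EBP at 184 ± 21.3 against 148 ± 19.8 FPKM and SQLE at 59.3 ± 2.85 against 71.4 ± 8.84 FPKM. With the trend with canonical, median or coding length removed the means were 0.099, 0.080 and 0.10 for fatty acid synthesis and 0.051, 0.054 and 0.057 for cholesterol synthesis. Both synthesis means were negative after rescaling to the same sum (-0.081 and -0.081), where the median of all genes was -0.13. The lipid-responsive genes were PLIN2, at 4.89 ± 0.213 against 5.27 ± 0.349 FPKM, ANGPTL4, at 5.27 ± 0.421 against 5.33 ± 0.629 FPKM, and PDK4, which was below the tested level.

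Stress response lists did not pass either. The mean log2 difference was -0.054 ± 0.032 for ATF4 targets (adjusted p = 0.510; 0.0436 at the preset correlation after quantile normalization) and -0.047 ± 0.034 for the unfolded protein response (adjusted p = 0.510). It was -0.063 ± 0.039 for hypoxia genes (adjusted p = 0.418), -0.075 ± 0.065 for p53 targets (adjusted p = 0.556) and 0.015 ± 0.027 for NRF2 and antioxidant genes (adjusted p = 0.419). The antioxidant mean turned to -0.10 after rescaling to the same sum, -0.022 after quantile normalization and -0.015 with the length trend removed. Rescaling gave -0.17 for ATF4 targets, -0.16 for the unfolded protein response, -0.18 for hypoxia and -0.19 for p53 targets, against a median of all genes of -0.13. Adjusted over the antioxidant list alone, 2 members were higher and 1 lower. The metallothionein genes MT2A (212 ± 7.87 against 158 ± 25.03 FPKM) and MT1X (26.2 ± 2.19 against 19.9 ± 0.497 FPKM), whose family shares sequence, were the higher ones. GCLC, of glutathione synthesis, was the lower one (22.9 ± 1.74 against 30.3 ± 2.65 FPKM). The chaperone gene CANX was at 284 ± 15.2 against 342 ± 21.9 FPKM, VEGFA at 15.7 ± 0.859 against 20.9 ± 2.59 FPKM and MDM2 at 33.5 ± 2.33 against 47.5 ± 12.3 FPKM.

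Most markers of other cell types lay below the tested level in both groups. The adipocyte genes ADIPOQ, FABP4, PLIN1 and LPL reached at most 0.0180, 0.117, 0.135 and 0 FPKM in any library. Of the markers listed in the table, 4 of 16 for adipocytes, 3 of 11 for endothelium and 2 of 6 for red cells reached that level, too few for a list test. The adipocyte ones include ADIRF (161 ± 2.98 against 179 ± 17.0 FPKM) and PPARG (31.8 ± 1.71 against 33.2 ± 3.26 FPKM). The others include the endothelial gene EGFL7 (151 ± 6.07 against 129.9 ± 16.2 FPKM) and the hemoglobin gene HBA1 (12.8 ± 1.76 against 9.97 ± 2.14 FPKM), which shares reads with HBA2. Fibroblast markers (5 tested, mean 0.14 ± 0.077, adjusted p = 0.398) and immune markers (5 tested, mean 0.061 ± 0.062, -0.021 after rescaling to the same sum, -0.044 with the length trend removed, adjusted p = 0.719) did not pass. Adjusted over the fibroblast list alone, 1 member was higher, the matrix protein gene MGP (15.4 ± 1.27 against 9.36 ± 1.60 FPKM). The fibroblast gene APOD was at 113 ± 6.53 against 111 ± 24.99 FPKM, and the collagen genes COL1A2 and COL3A1 reached at most 0.155 and 0.365 FPKM.

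The difference between the groups followed transcript length. Across 11579 genes, which are not independent replicates, the log2 difference correlated with canonical transcript length at a Spearman's rho of -0.46 and with GC content at 0.28. The median log2 difference was 0.19 for the 132 genes of up to 500 nt and -0.17 for the 918 genes over 8000 nt. The slope of a library's deviation from the gene mean, in log2 units per 10-fold length, was -0.146 ± 0.0314 in O-EV and 0.146 ± 0.145 in PBS (two-sided exact permutation p = 0.1, the smallest possible; 0.14 adjusted over 7 library measures). Removing the length trend took away over 50% of the log2 difference of 20 of 90 named genes that were higher in O-EV and of 4 of 57 that were lower. PBS replicate 1, with a slope of -0.0118, lay between the O-EV libraries and the other 2 PBS libraries, at 0.275 and 0.174. Pearson's r between libraries was 0.983 to 0.985 within O-EV, 0.985 to 0.990 within PBS and 0.981 to 0.986 between the groups. The between-group values overlap both within-group ranges.

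**Figure D3:**
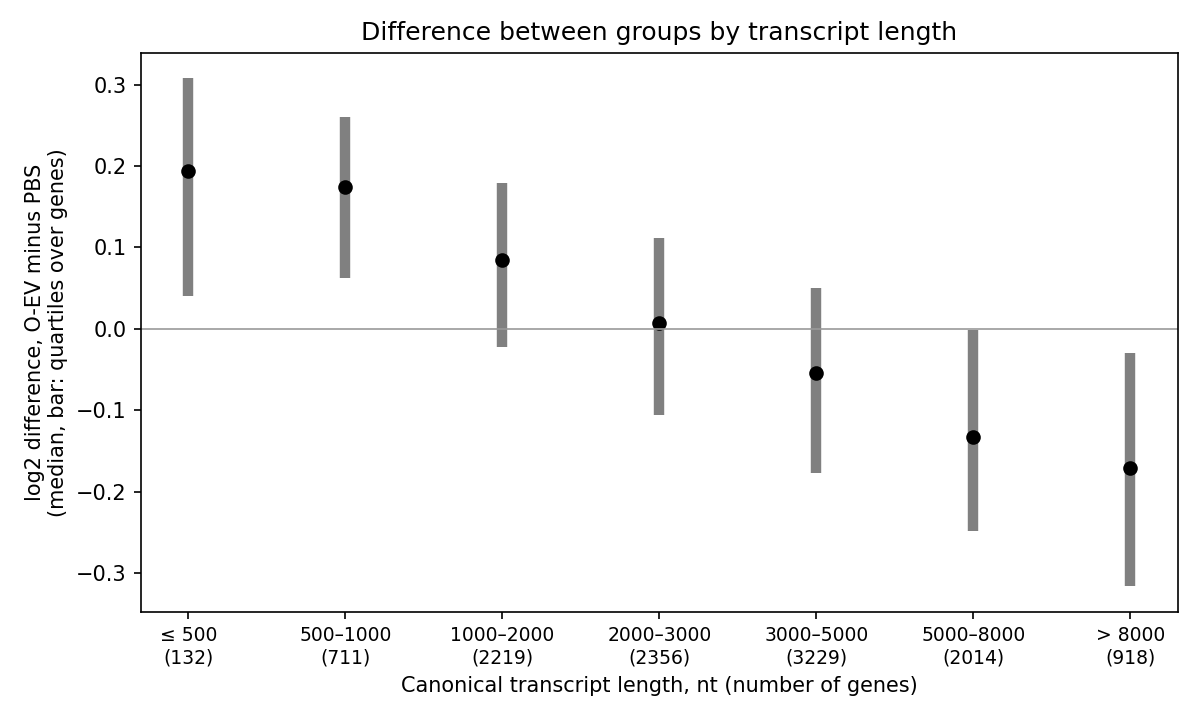
Median log2 difference between O-EV and PBS (points) and its quartiles over genes (grey bars) for 7 classes of canonical transcript length in nucleotides, with the number of genes in each class. The median goes from 0.19 in the shortest class to -0.17 in the longest.

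**Figure D4:**
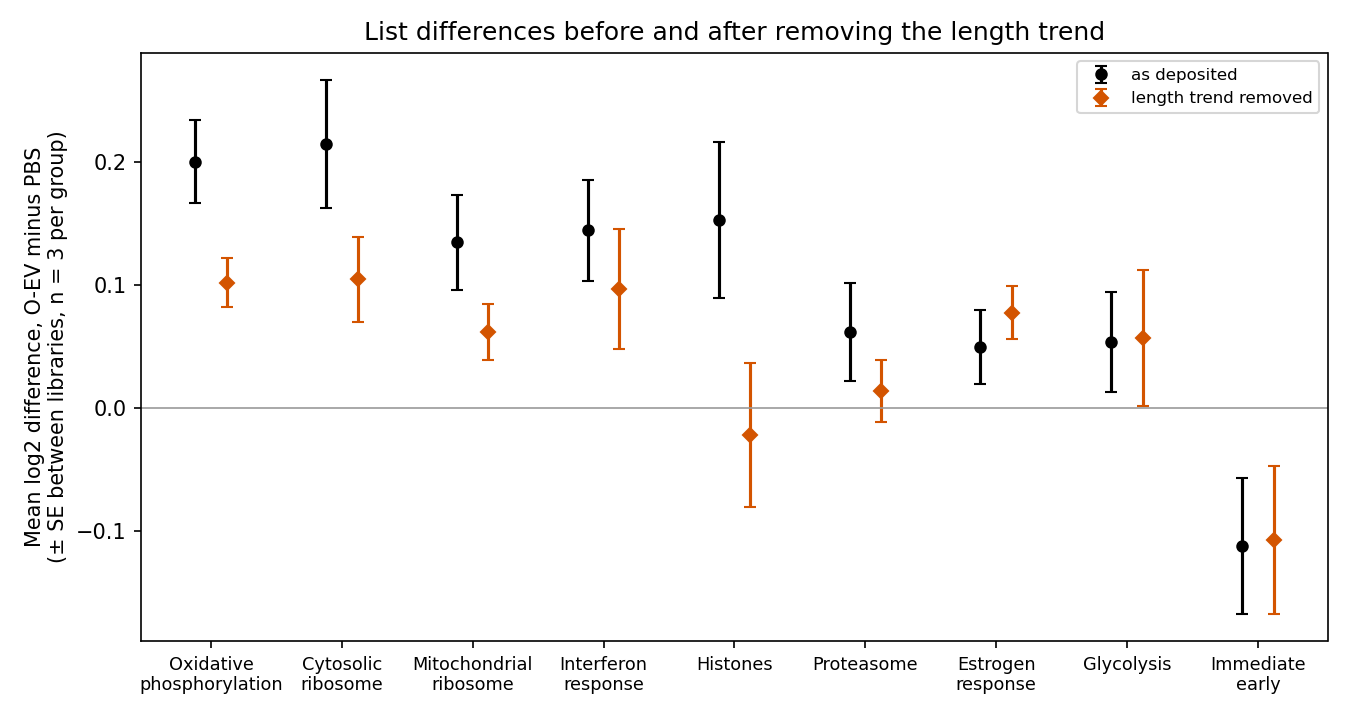
Mean log2 difference between O-EV and PBS of 9 gene lists as deposited (black circles) and with each library's trend with canonical transcript length removed (orange diamonds); bars are SE between libraries, n = 3 per group. Oxidative phosphorylation goes from 0.20 to 0.10 and histones from 0.15 to -0.022.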

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

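The corrections for transcript length, by 3 measures of length, and for GC content were chosen after the data were seen, as was the length correction with an estimated correlation. The p-values below are adjusted over the lists. Only relative depth is known, so no floor can be given for low genes, whose values rest on few reads most of all in O-EV replicate 3, the shallowest library (0.827 of their geometric mean). No gene passed with all 6 libraries, except under 2 settings: MIR3648 (adjusted p = 0.0296) was the 1 lower gene with a pseudocount of 0.1 FPKM, and FXYD1 (adjusted p = 0.0431) was the 1 lower gene with no filter on low values. Both genes are named after their values were seen. The lists for complexes I, IV and V and for oxidative phosphorylation as a whole passed under 14 of 16 alternatives that kept all 6 libraries. The mitochondrial ribosome passed under 13 and the cytosolic ribosome under 12. Interferon and histones each passed under 11, complexes II and III under 10, proteasome under 9, estrogen response under 8 and glycolysis under 5. Most of these alternatives kept the preset correlation of 0.01, so they do not test that setting. Among these 16, complexes I, IV and V and oxidative phosphorylation lost their calls only where the correlation was estimated. They also lost them with fry and the length trend removed together, which is not among the 16 (adjusted p = 0.0656 for each). The estimate was 0.14 for oxidative phosphorylation and 0.33 for the cytosolic ribosome. The cause of each change below was not tested.

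With an inter-gene correlation estimated per list, 0 lists passed: complex I (0.164), complexes II and III (0.270), complex IV (0.164), ATP synthase (0.164), oxidative phosphorylation (0.164), mitochondrial ribosome (0.270), glycolysis (0.545), estrogen response (0.312), cytosolic ribosome (0.270), interferon (0.276), proteasome (0.343) and histones (0.376). With the length trend removed as well, 0 passed: complex I (0.277), complexes II and III (0.366), complex IV (0.330), ATP synthase (0.330), oxidative phosphorylation (0.277), mitochondrial ribosome (0.366), glycolysis (0.564), estrogen response (0.366), cytosolic ribosome (0.366), interferon (0.564) and proteasome (0.641). The lists that also turned were antioxidant (0.772), mitochondrial biogenesis (0.920), immune markers (0.688) and histones (0.852). With fry, which does not compare a list with other genes and passed 4 lists, the calls lost were complexes II and III (0.0584), mitochondrial ribosome (0.0787), glycolysis (0.239), estrogen response (0.194), cytosolic ribosome (0.0584), interferon (0.0861), proteasome (0.237) and histones (0.182). The lists whose direction turned were PI3K components (0.955) and mitochondrial biogenesis (0.832). With the trend with canonical transcript length removed, the calls lost were complexes II and III (0.0855), glycolysis (0.0651), interferon (0.151) and proteasome (0.630). The lists whose direction turned were antioxidant (0.692), mitochondrial biogenesis (0.924), immune markers (0.630) and histones (0.692). The genes whose log2 difference changed sign were APOD (-0.093) and CPT1A (0.059). The lower genes at an unadjusted p under 0.05 numbered 554. With the trend with coding length removed, the calls lost were complexes II and III (0.121) and histones (0.534). The lists whose direction turned were fatty acid oxidation (0.948), cell cycle (0.440), antioxidant (0.991) and immune markers (0.844). The genes whose log2 difference changed sign were GSN (0.039), APOD (-0.025), GREB1 (0.0091), CPT1A (0.040) and ANGPTL4 (0.0070). The lower genes at an unadjusted p under 0.05 numbered 571. With the trend with the median length of a gene's coding transcripts removed, the calls lost were glycolysis (0.111), estrogen response (0.0930) and proteasome (0.0930). The genes whose log2 difference changed sign were GSN (0.017), APOD (-0.0084) and FBLN1 (-0.018). With the GC trend removed, the call lost was glycolysis (0.114). The lists whose direction turned were fatty acid oxidation (0.897), cell cycle (0.408) and mitochondrial biogenesis (0.993). The genes whose log2 difference changed sign were PPARG (0.037) and CPT1A (0.00096). After quantile normalization, the calls lost were complexes II and III (0.350), estrogen response (0.450) and cytosolic ribosome (0.188). The lists whose direction turned were glycolysis (0.520), PI3K components (0.520), NF-kappaB (0.868), antioxidant (0.407), proteasome (0.450) and mitochondrial biogenesis (0.520). The genes whose log2 difference changed sign were PSMB4 (-0.028), APOD (-0.024), ESAM (0.050), PLIN2 (0.0051) and ANGPTL4 (0.078). After rescaling each library to the same sum, the calls lost were glycolysis (0.280), estrogen response (0.0941) and proteasome (0.332). The list whose direction turned was mitochondrial biogenesis (0.665). The genes whose log2 difference changed sign were SOD2 (-0.020), APOD (-0.077), FBLN1 (-0.070) and TFAM (-0.072). The genes at an unadjusted p under 0.05 were then 265 higher and 1960 lower, 11.9% higher against 52.1% as deposited. The median log2 difference of all genes was then -0.13. After median-ratio scaling, the gene whose log2 difference changed sign was ANGPTL4 (0.0027). With a mean of at least 5 FPKM, the calls lost were glycolysis (0.0946) and estrogen response (0.1002). The lists whose direction turned were PI3K components (0.840), NF-kappaB (0.840) and mitochondrial biogenesis (0.840). With no filter on low values, the call lost was interferon (0.144). The list whose direction turned was NF-kappaB (0.901). With eBayes without the intensity trend, the call lost was glycolysis (0.0662). Of 30 list means, 5 changed sign and 4 grew over 1.5 times with the canonical length trend removed, 2 and 3 with the median length, 7 and 5 with the coding length, 4 and 7 with the GC trend, 9 and 11 after rescaling, and 4 and 4 after quantile normalization. Among them, the sign of the PI3K components changed with each length measure and that of the unfolded protein response (0.0017) with the GC trend, without a turn of the list test. Lists that did not pass as reported passed under some alternatives: immediate early with no filter (0.0443) and with the canonical length, coding length and GC trends removed (0.0154, 0.0186 and 0.00822), ATF4 targets and luminal genes after quantile normalization (0.0436 and 0.00752), and the tricarboxylic acid cycle with the GC trend removed (0.0153). Over the named genes and all alternatives, single-library omissions included, 2772 log2 differences kept their direction and side of the threshold, 40 changed sign and 3 gained a call.

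The libraries share replicate numbers, which the labels do not explain. The deviations of same-numbered libraries from their group means correlated at -0.034, -0.062 and 0.096, and only replicate 3 correlated best with its own number. This does not show a pairing by number, and with 3 libraries per group it does not exclude one. With the replicate number as a block, 0 genes passed in either direction and 10 lists passed. The block left 1441 genes at an unadjusted p under 0.05, 48.0% of them higher in O-EV. Under the block glycolysis (0.0618) and estrogen response (0.0583) missed the threshold, and NF-kappaB (0.988) and mitochondrial biogenesis (0.961) turned.

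Leaving out each library in turn gave 0 to 2 higher and 0 to 4 lower genes past the threshold, most of them small nucleolar or other small RNA genes. At an unadjusted p under 0.05, 510 to 1236 genes were higher and 391 to 1356 lower. The higher ones numbered 625 without O-EV replicate 2, 510 without PBS replicate 2 and 573 without PBS replicate 3. The lower ones numbered 1356 without PBS replicate 1, 391 without PBS replicate 2 and 459 without PBS replicate 3. From 10 to 12 lists passed. The adjusted p ranged over 0.00860 to 0.167 for estrogen response, 0.00382 to 0.206 for glycolysis and 0.000204 to 0.0633 for proteasome, each of which lost its call in at least 1 of these 6 fits. The lists that turned ranged over 0.703 to 0.983 for cell cycle, 0.610 to 0.968 for fatty acid oxidation, 0.484 to 0.895 for fatty acid synthesis, 0.776 to 0.946 for NF-kappaB, 0.484 to 0.964 for luminal, 0.704 to 0.973 for mitochondrial biogenesis and 0.594 to 0.974 for PI3K components. The log2 differences that changed sign ranged over -0.11 to 0.020 for PPARG, -0.15 to 0.024 for GSN, -0.054 to 0.22 for APOD, -0.12 to 0.16 for FBLN1, -0.13 to 0.60 for EMCN, -0.14 to 0.042 for ESAM, -0.063 to 0.14 for TFAM, -0.092 to 0.0049 for CPT1A and -0.060 to 0.069 for ANGPTL4. A single omission moved the mean of 3 of 12 called lists (glycolysis, estrogen response and proteasome), of 17 of 18 lists that did not pass, and the log2 difference of 35 of 150 named genes by over 1.5 times. ACHE passed without O-EV replicate 2 (log2 2.33, adjusted p = 0.00875).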

Other observations

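The tests of length as the whole of a difference, and the genes in this paragraph, were chosen after the values were seen. None of the 3 long noncoding RNAs named here passed the adjusted threshold. NEAT1, the nuclear RNA around which paraspeckles form, was at 8.57 ± 0.473 FPKM in O-EV against 16.1 ± 4.20 in PBS (log2 -0.81 ± 0.17; -0.59 with the length trend removed). On GRCh37 it lies on chromosome 11, 65190245 to 65213011, plus strand. Its neighbour MALAT1, which is overlapped by an antisense gene, was at 5.41 ± 1.64 against 9.35 ± 3.91 FPKM (log2 -0.65 ± 0.30, and -0.39 without PBS replicate 2), with overlapping groups. DSCAM-AS1, a long noncoding RNA abundant in luminal breast cancer cells, was at 479 ± 34.3 against 355 ± 25.3 FPKM (log2 0.43 ± 0.079). It lies antisense to DSCAM, and since no strand setting is known the values of both genes with an antisense partner are uncertain. MIR3648, a short RNA gene on chromosome 21, was listed at 0 in all 3 O-EV libraries and at 5.73, 2.23 and 2.56 FPKM in PBS. It was lower past the threshold with a pseudocount of 0.1 FPKM (adjusted p = 0.0296) and without PBS replicate 1 (limma, adjusted p = 0.0276). A poly(A) library measures so short a gene poorly.

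The nuclear genes of oxidative phosphorylation were higher in O-EV by a mean of 0.20 ± 0.034, and by 0.24 ± 0.052 with the GC trend removed, which argues against GC content. Removing the length trend, by any of 3 length measures, left at least 0.10 ± 0.020 and took away 49.0%, 21.9% or 46.1%. This argues against length, as measured here, as the whole of the difference. The measures come from a later annotation and may not match the transcripts expressed. A trend on misstated lengths would be removed only in part, so length as the whole is not excluded. The part that goes with length cannot be told apart from the treatment. With the canonical and coding lengths the mean was not above a bound of 0.1 by more than its SE, while with the median transcript length it was (0.16 ± 0.025). Random lists matched on length and expression averaged 0.14, 71.7% of the list's mean and a larger share than the corrections took away. Lists matched on expression alone averaged 0.10. The list lay at percentile 100 of 10000 lists of either kind. The genes drawn could belong to other called lists, ribosomal genes included, which can raise that share. They were drawn independently, so the percentile makes no allowance for correlation between genes. Rescaling to a common sum left 0.081 ± 0.013, and the list minus the median of all genes went from 0.22 to 0.21. Rescaling divides each library by 1 number, so this height could hardly change whatever the data. It therefore does not test the FPKM sum as the source of that height. After quantile normalization, which can change the height, the list mean was 0.095 and the median of all genes 0.0061. For the size of the mean itself, the sum goes with the groups and stays open. An effect of the vesicles also stays open, which may be biological and was not tested apart from these. The list mean was largest in 1 of 10 splits of the libraries, the real one, at 0.20 against 0.11 for the next, and 10 splits are too few for a share under 0.05.

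The cytosolic ribosomal protein genes were higher by a mean of 0.21 ± 0.052, and by 0.26 ± 0.073 with the GC trend removed, which argues against that trend. Removing the length trend left at least 0.10 ± 0.035 and took away 51.2%, 25.1% or 41.6%. This argues against length, as measured here, as the whole of the difference. It does not exclude it, since the lengths may not be those of the transcripts expressed. RPL37, with a canonical length of 7573 nt, went from log2 0.40 to 0.55 under that correction. Lists matched on length and expression averaged 0.157, 73.3% of the list's mean, with the list at percentile 100. Lists matched on expression alone averaged 0.158, also with the list at percentile 100, so that share need not go with length. The limits of matched lists given above hold here too. The part that goes with length cannot be told apart from the treatment, since only with the median transcript length was the mean above 0.1 by more than its SE (0.16 ± 0.041). Rescaling to a common sum left 0.094 ± 0.026 (0.23 and 0.22 above the median of all genes before and after). As above, dividing each library by 1 number could hardly change that height, so this does not test the FPKM sum as its source. After quantile normalization, which can change it, little of the height remained. The list mean was then 0.023 and the median of all genes 0.0061 (camera, adjusted p = 0.188). For the size of the mean the sum stays open, as does an effect of the vesicles. Of 10 splits, 1 gave a mean as large, the real one, at 0.21 against 0.14 for the next, again too few splits for a share under 0.05.

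Of the 10 splits of the 6 libraries, 1 gave as many genes at an unadjusted p under 0.05 as the real one (1801, against 1086 for the next), and so few splits cannot give a share under 0.05. At an adjusted p under 0.05 the real split gave 0 genes and the others up to 3, but with 0 in the real split all 10 give at least as many whatever the data, so that count decides nothing. In the split with 1086 genes, PBS replicates 2 and 3 stood with O-EV replicate 1. PBS replicate 1 had a length slope of -0.0118, nearer to the O-EV libraries than those of PBS replicates 2 and 3 were, and a mean deviation of -0.067 over the oxidative phosphorylation genes, against -0.14 and -0.090 in the other PBS libraries and 0.082, 0.15 and 0.068 in O-EV. PBS replicate 2 had the highest relative depth (1.24) and the highest length slope (0.275) of the 6 libraries.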
